A study of Mus musculus with 66 samples.

How the data were processed

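Single cells of mouse bone marrow, sorted as lineage-negative, CD117-positive and CD34-positive, were separated on a Fluidigm C1 chip, copied into cDNA with the SMARTer chemistry and made into Nextera XT libraries, per the labels' protocols. Reads from such libraries cover whole transcripts and carry no molecular identifiers, so copies made by amplification cannot be told from separate molecules. Bowtie2, RSEM and the genome build mm9 are named in the submitters' processing notes, with no versions. The annotation and any filter on genes or cells are not given in the sources used here. The authors deposited 1 table of log2 values, 23955 genes by 66 cells. No header names the unit. It was read from the values: none was below 0, and 2 to the power of the value, less 1, summed to 1000000 in every cell, as log2(TPM + 1) does. The smallest value above 0 was 0.01 TPM. TPM keeps no count of reads, so the depth per cell is unknown, no counting floor per gene can be given, and a 0 in the table is described as listed at 0.

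Each column carries the number of a cell, which was matched to the cell number in the labels, and 0 columns were left unused. The 3 cells the labels mark as poor quality were kept apart, and 63 cells entered the main values. The labels name no animal, so the cells were treated as 1 sample. Means are given with the SD over cells, which is the spread between cells and not an error of the mean, and zeros are included. Shares of cells have exact Clopper-Pearson intervals (95%), for counting error only. Doublets were not called.

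A gene was counted as present in a cell at or above 1 TPM. A list was counted as present where at least 3 members were. The 10 marker lists were stem and multipotent progenitor, megakaryocyte, erythroid, primary granule, late granulocyte, monocyte, dendritic, eosinophil, basophil and mast, and lymphoid progenitor. The other lists were mature B, T and NK, tissue macrophage, stroma and endothelium, S phase, G2/M, immediate early and stress, housekeeping, X inactivation, Y linked, gate antigens and 53 transcription factors. The gate antigens Ly6g and Ter119 matched no gene symbol of the table. List spread was the SD over cells of the mean log2(TPM + 1) of the members, set against 10000 random lists of the same size matched on mean expression in 20 bins, as a percentile that describes these libraries. Genes listed at 0 in all cells were left out of it. For mixed lineages, cells with at least 3 members at or above 10 TPM of each of 2 lists were counted beside the product of the shares. For 15 pairs of transcription factors, the number of cells with both was set against 10000 random gene pairs whose detection counts lay within 2 cells of those of the pair. For genes present in few cells this window is wide relative to the count, and includes genes present in none.

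Clusters were made from the 500 genes of highest SD among 9487 genes present in at least 5 cells, without the transcription factor, cell cycle, stress, Y linked and X inactivation lists. The first 10 principal components (the first held 27.5% of the variance) were joined by Ward linkage, and the tree was divided at the largest number from 2 to 8 that left at least 5 cells per cluster. Clusters are numbered by size. A cluster was named only where markers fixed in advance led it. For clusters 1, 2, 4 and 5, leading genes by fold were often present in few cells, so the leading genes among those present in at least 50% of the cells were also looked at, a choice made after seeing the data.

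Genes named in the text follow a rule. It takes all gate antigens, the 3 members of each list with the highest mean and the 3 with the highest SD, members of the fixed pairs and the 6 other transcription factors with the largest difference between cluster means. It also takes the 10 genes highest by mean TPM, the 20 highest by SD among genes present in at least 10% of cells and the 10 leading genes of each cluster by fold. Genes named outside this rule are said to have been chosen after their values were seen. The marker lists, pairs, main levels and the rule were set before the data were examined, and sets or levels chosen later are named as such where they are used.

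The reference at hand was GRCm38 with GENCODE M21, a later build than mm9, so no coordinates are given and only gene symbols and transcript sequences were used. Shared sequence was measured as the number of 31-base words of a gene's longest transcript that occur in at least 10 other genes, and 50 such words marked a gene as sharing sequence. Among marker and transcription factor genes, 9 of 190 with a sequence were so marked, Cd34 among them.

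The steps were tested on simulated data made by shuffling the values of genes over cells, 13261 genes for the lists and pairs and 9573 for the clustering. Of 200 lists of 12 genes given a shared factor, 100% lay above the central 95% of matched lists in spread, against 1.5% of 200 lists without one. These lists were drawn from genes present in at least 10% of cells, so the shares do not cover lists of genes present in few cells. Of 200 pairs made exclusive, 100% lay below the central 95% of matched pairs, against 1% of 200 independent pairs. These pairs were drawn from genes present in an intermediate number of cells, so the shares do not cover pairs with a gene present in few cells. For such pairs 0 shared cells can lie inside the central 95%, as for Gata1 with Spi1 (percentile 8.66). With 4 simulated groups of cells, each with 100 genes raised 64-fold, the clustering at 4 clusters gave the groups exactly (adjusted Rand index 1), but the rule for the number of clusters gave 7, each holding cells of 1 group. On values with no groups it gave 8. The rule therefore divides too finely, and the number of clusters is not used as a result.

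Alternatives were other detection levels, numbers of members, pseudocounts (0.1 and 10 in place of 1), filters, rescaling by the median ratio over 310 genes with a value in every cell, numbers of variable genes (250 and 1000), another linkage, the number of clusters of highest silhouette, and all 66 cells. Alternatives chosen after seeing the data raised each gene's level to 1% of its mean over cells, left out 4 cells under 2500 genes (all 4 in cluster 3), or took cluster 1 alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.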

Results

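The series holds 66 single-cell RNA-seq libraries of mouse bone marrow (C57BL/6, a common inbred strain). The cells had been sorted as negative for lineage antigens and positive for CD117 (the receptor encoded by Kit) and CD34. The labels describe the gate as broad, reaching from stem and progenitor cells to late stages of the granulocyte line. Single cells were separated on a microfluidic chip and copied into cDNA by template switching. The labels mark 3 of the cells, numbers 3, 8 and 11, as being of poor quality, and the values below come from the other 63. No animal or culture is named, so the 63 cells count as 1 sample: no test was made between cells, and intervals on shares of cells are exact Clopper-Pearson intervals (95%) that cover counting error only. The values are in TPM, an abundance scaled for transcript length and to the same total in every cell. They keep no record of read depth, so the depth per cell is unknown. The 63 cells had a median of 4484 genes at or above 1 TPM, with a range from 1544 to 6503. The 3 poor-quality cells had 586, 1262 and 322.

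The first question was whether the sorted antigens were seen as transcripts. Kit was at or above 1 TPM in 38 of 63 cells (60.3%, interval 47.2 to 72.4), with a mean log2(TPM + 1) of 2.99 ± 2.76 (SD over cells, here and below). Cd34, a surface sialomucin of progenitors, was found in 34 cells (54.0%, interval 40.9 to 66.6) at 3.73 ± 3.92. Both transcripts were present in 25 cells, Kit alone in 13, Cd34 alone in 9 and neither in 16. Part of the Cd34 transcript (84 of its 31-base words) is shared with 10 or more other genes, so low Cd34 values are uncertain. Of the antigens the lineage stain was meant to remove, Cd3e, Cd4 and Cd19 were listed at 0 in all 63 cells. Cd8a reached 1 TPM in 2 cells, with a maximum of 6.32 TPM. Itgam, which encodes CD11b and also belongs to that stain, was found in 24 cells (38.1%, interval 26.2 to 51.2).

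The other stained antigens ranged widely. Ptprc, the pan-leukocyte antigen CD45, was found in 52 cells, and Ly6a, which encodes Sca-1, in 54. The Fc receptor genes Fcgr2b and Fcgr3 were found in 41 and 48 cells. Csf1r, the macrophage colony-stimulating factor receptor, was found in 21 cells and Flt3 in 4. Siglec5, the symbol used for the eosinophil antigen Siglec-F, was found in 8 cells, while Ccr3 was listed at 0 in all. Ly6c1 was found in 55 cells and Ly6c2 in 60, Ly6c2 with a median of 4040 TPM. With detection set at any value above 0 TPM, the share with Kit was 74.6% and that with Cd34 68.3%.

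Lists of lineage genes fixed in advance showed which programmes the gate held. Primary granule genes, which mark granulocyte-monocyte progenitors, reached 100 TPM for at least 3 members in 58 of 63 cells. Among them, Mpo (myeloperoxidase) had a median of 15503 TPM, Elane (neutrophil elastase) 12670 TPM and Plac8 5137 TPM. Mpo was at or above 100 TPM in 49 cells, Elane in 46 and Plac8 in 59. The 58 cells include 7 of the 10 of cluster 3, described below, where Mpo and Elane had medians of 2.2 and 3.8 TPM. Late granulocyte genes reached 100 TPM for at least 3 members in 48 cells and monocyte genes in 54. Among the late granulocyte genes, Serpinb1a was at or above 100 TPM in 56 cells, Hp in 51, S100a8 in 32, S100a9 in 25, Camp and Ngp in 19 each and Gstm1, named after its values were seen, in 43. The 48 cells include 21 of the 26 cells of cluster 1, described below, where the list averaged 2.92 ± 0.82, and all 10 of cluster 3, where it averaged 9.69 ± 0.38. The highest monocyte list members were Ly6c2, Tyrobp (median 1171 TPM) and the lysozyme gene Lyz2 (611 TPM), at or above 100 TPM in 55, 56 and 47 cells. Ms4a6c was at that level in 23 cells, Ly86 and F13a1 in 22 each and Csf1r in 10, and the 54 cells include all 10 of cluster 3, where Csf1r was in 0. Without the most widely found members, an alternative chosen after seeing the data, 100 TPM was reached in 27 cells for the late granulocyte list (without Serpinb1a, Hp and Gstm1) and 25 for the monocyte list (without Ly6c2, Tyrobp and Lyz2), 0 of the 25 in cluster 3. At the detection level fixed in advance, 3 members at or above 1 TPM, the primary granule and late granulocyte lists were found in all 63 cells (interval 94.3 to 100%) and the monocyte list in 59 (93.7%, interval 84.5 to 98.2). Abundant granulocyte transcripts were also listed at low level in cells where they were not abundant (S100a8 at a median of 18.3 TPM in cluster 4, described below), and counts at 1 TPM include such values. With each gene's level raised to 1% of its mean over the cells, an alternative chosen after seeing the data, 60 cells had the primary granule list, 52 the late granulocyte list and 58 the monocyte list.

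At least 3 genes of the stem and multipotent progenitor list were found in 48 cells (76.2%, interval 63.8 to 86.0), led by Cd48, Ly6a and Cd34. Cd48 was present in 50 cells, Cd27 in 18, and Ly6a also in all 10 cells of cluster 3. Among members named after their values were seen, Ctla2a, which shares sequence with other genes as Cd34 does, was in 51 cells, Eltd1 in 25 and Angpt1 in 10. Of the others so named, Mpl was in 2, Slamf1, Esam and Sult1a1 in 1 each, and Procr and Fgd5 in 0. Without Cd48, Ly6a, Cd34 and Ctla2a, also an alternative chosen after seeing the data, 8 cells had the list, so the share is no count of stem cells. Erythroid genes were found in 17 cells (27.0%, interval 16.6 to 39.6) and megakaryocyte genes in 9 (14.3%, interval 6.75 to 25.4). Tfrc, the transferrin receptor of dividing as well as erythroid cells, was in 38 cells, Minpp1 in 22, and the carbonic anhydrase gene Car2 in 13. The megakaryocyte list was led by Cd9 (36 cells) and Serpine2 (22 cells), whereas Pf4, which encodes platelet factor 4, reached 1 TPM in 5 cells. Dendritic genes were found in 11 cells (17.5%, interval 9.05 to 29.1). Their highest member, Cst3 (cystatin C), was in 62 cells, Bst2 in 28 and the class II gene H2-Ab1 in 11. The other members were named after their values were seen. Xcr1, which shares sequence with other genes, was in 6 cells, and Siglech, Cd74 and H2-Eb1 were in 1 each. H2-Aa, Ccr9, Itgax, Clec9a, Cd209a and Klrd1 were in 0, so the share is no count of dendritic cells.

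No cell had 3 members of the eosinophil, basophil and mast, or lymphoid progenitor lists at or above 1 TPM. Single members were present. Hdc, which encodes the enzyme that makes histamine, was in 37 cells, Mcpt8 in 12 and Cpa3 in 4. Cd79b, a component of the B cell receptor, was in 26 cells and Notch1 in 25, while Ear2, an eosinophil ribonuclease, was in 6. The mature B, T and NK, and stroma and endothelium lists were found in no cell, and the tissue macrophage list in 1. Vcam1 was in 16 cells and Emr1, the F4/80 antigen, in 4. Lepr, the leptin receptor gene of the stroma list, was at or above 1 TPM in 46 cells at a median of 1.94 TPM, and its transcript shares 52 of its 31-base words with 10 or more other genes. Listed in no cell were 1 of 14 stem and multipotent progenitor genes, 2 of 17 megakaryocyte, 3 of 20 erythroid, 5 of 13 dendritic, 4 of 10 eosinophil and 4 of 8 tissue macrophage genes. The same held for 6 of 11 basophil and mast genes, 8 of 12 lymphoid progenitor genes, 4 of 6 mature B genes, 7 of 10 T and NK genes and 7 of 11 stroma and endothelium genes.

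The second question was which list means varied over cells more than those of random lists. Matching was on mean expression and not on the SD of single genes. A list of highly variable genes can therefore lie high without its members moving together. The mean of the primary granule list had an SD of 3.40 over cells, against a median of 1.29 in 10000 random lists matched on mean expression. The late granulocyte list had an SD of 2.98 against 0.96, and the monocyte list 1.63 against 0.86. All of these exceeded every matched list, as did the erythroid list (0.74 against 0.40) and the megakaryocyte list (0.76 against 0.39). With only genes present in at least 10% of cells, the erythroid list lay at percentile 97.76 and the megakaryocyte list at 99.25. The highest single cells had erythroid and megakaryocyte list means of 3.71 and 4.19, against 0.55 and 0.59 over all cells. The stem and multipotent progenitor list lay at percentile 97.1, the eosinophil list at 96.3, the lymphoid progenitor list at 64.8, the basophil and mast list at 60.3 and the dendritic list at 24.4. Housekeeping genes lay at percentile 14.7. Within them Actb (12.81 ± 0.75) and Ppia (12.77 ± 0.74) were at or above 1 TPM in every cell, and Tbp in 28 cells. The tissue macrophage list lay at percentile 98.5 with 4 members seen, and the mature B, T and NK, and stroma and endothelium lists at percentiles 0.88, 0.31 and 1.67.

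Granulocyte transcripts dominated both the highest and the most variable genes. By mean TPM the first were S100a8 (41809), Ngp (23599), S100a9 (21464), Elane (16945), Camp (16796) and Mpo (14634), followed by Ubb, Eef1a1, Actb and Ppia. S100a8 and S100a9 encode the subunits of calprotectin, Camp the antimicrobial peptide cathelicidin, and Ngp a neutrophil granule protein. S100a8, S100a9, Ngp and Camp together took over 10% of TPM in 16 cells, a median of 0.0208% over all 63, and 58.8% in the highest cell. Of the 20 genes with the highest SD of log2(TPM + 1), Camp (6.14), S100a9 (6.07), Ngp (5.87) and S100a8 (5.85) were first. Chil3, Lcn2, Fcnb, Ltf and Gstm1 of the late granulocyte list, Elane, Mpo, Ctsg and Prtn3 of the primary granule list, and Ly86 and F13a1 of the monocyte list were also among them. The remaining members were 1100001G20Rik, Pglyrp1, Cd63, Plp2 and Rps27, the last encoding a ribosomal protein.

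**Figure D1:**
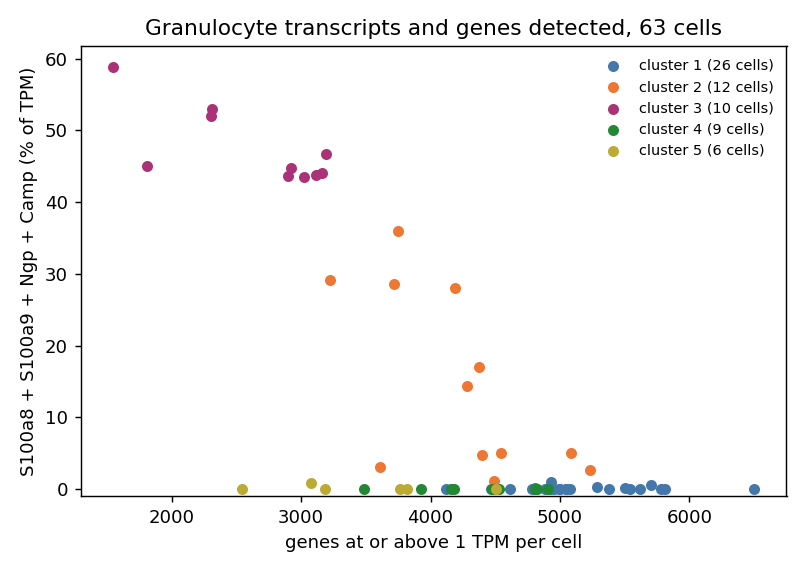
Each point is 1 of 63 cells, with the genes at or above 1 TPM on the x axis and the summed share of S100a8, S100a9, Ngp and Camp in percent of TPM on the y axis, coloured by cluster. The 10 cells of cluster 3 lie between 43.5 and 58.8% and have a median of 2911 genes, and those of cluster 2 spread from 1.18 to 36.0%.

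Clustering without transcription factor, cell cycle, stress and sex-linked genes gave 5 clusters of 26, 12, 10, 9 and 6 cells. Cluster 3 was late-granulocyte-like: Ltf (lactoferrin), Lcn2 (lipocalin 2), Stfa1 and Olfm4 of that list were among its 10 leading genes by fold, although Stfa1 was in 2 and Olfm4 in 1 of its 10 cells. The other clusters are given by number, since none of their 10 leading genes belonged to a listed type in clusters 1, 2 and 5. Car1, Hbb-b1 and Esam were among the leading genes of cluster 4 but came from 2, 1 and 1 of its 9 cells. The primary granule list averaged 11.29 ± 0.78 in cluster 1, 11.44 ± 0.95 in cluster 2, 3.60 ± 1.25 in cluster 3, 6.98 ± 3.12 in cluster 4 and 9.06 ± 3.71 in cluster 5. The late granulocyte list averaged 2.92 ± 0.82, 7.06 ± 1.43, 9.69 ± 0.38, 1.78 ± 0.75 and 2.56 ± 0.96 in the same order. These lists contain genes that helped to form the clusters. The number of clusters is set by the rule used and is no evidence of as many cell types: the rule gave 8 clusters on shuffled values with no groups. The 10 cells of cluster 3 stayed in 1 cluster under all 6 alternatives that kept them, with no other cell under 3 of these and with 14, 12 and 3 other cells under average linkage, the silhouette rule and the use of all 66 cells. How the remaining cells were divided depended on the settings (adjusted Rand index with the clusters from 0.41 to 0.81).

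Gate antigens differed between these clusters. They had not been kept out of the clustering, so some of them may have helped to form the clusters. Kit was found in 19 of 26 cells of cluster 1, 8 of 12 of cluster 2, 0 of 10 of cluster 3, 6 of 9 of cluster 4 and 5 of 6 of cluster 5. Cd34 was found in 24 of 26, 1 of 12, 0 of 10, 6 of 9 and 3 of 6. Cluster 3 also had a median of 2911 genes against 4996 in cluster 1 and a housekeeping list mean of 8.16 against 10.53, so absence there is less certain. Itgam went the other way over clusters 1 to 3, with 2 of 26, 10 of 12 and 10 of 10 cells, and a level of 7.56 ± 1.86 in cluster 3 against 0.51 ± 1.45 in cluster 1.

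Transcription factors had been kept out of the clustering, so their levels did not define the clusters. Myc, a driver of growth and division, averaged 7.10 ± 2.85 in cluster 1, 2.16 ± 3.49 in cluster 2 and 0.03 ± 0.09 in cluster 3, where it reached 1 TPM in 0 of 10 cells. In clusters 4 and 5 it averaged 8.03 ± 3.21 and 7.22 ± 3.21. Irf8, a factor of monocyte and dendritic development, averaged 5.76 ± 3.50 in cluster 1, where 20 of 26 cells had it, and 0.14 ± 0.38 and 0.08 ± 0.13 in clusters 2 and 3. In clusters 4 and 5 Irf8 averaged 4.34 ± 3.75 (6 of 9 cells) and 1.28 ± 3.13 (1 of 6 cells). Cebpe, a factor needed for secondary granules, went from 1.86 ± 2.74 in cluster 1 to 4.79 ± 2.83 and 5.54 ± 2.84 in clusters 2 and 3. Id2 was at 0.91 ± 1.85, 6.41 ± 3.40 and 7.45 ± 2.70 in these clusters, and Ets1 at 1.32 ± 2.62, 4.55 ± 3.37 and 6.42 ± 3.40. Cebpa was in 19 of 26, 8 of 12 and 0 of 10 cells. Gfi1, a repressor needed for neutrophil formation, was in 10 of 26, 8 of 12 and 3 of 10.

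Other factors followed different lines. Per3, a circadian gene, was highest in cluster 2 (4.80 ± 2.23) and lowest in cluster 3 (0.35 ± 0.91). Mef2c was highest in cluster 4 (4.39 ± 3.20), and Myb ranged from 7.38 ± 1.17 in cluster 5 to 3.49 ± 2.80 in cluster 3. Spi1, which encodes PU.1, was in 20 of 26 cells of cluster 1 and 0 of 6 of cluster 5. Fli1 was in 60 of all 63 cells. Gata1, the erythroid and megakaryocyte factor, reached 1 TPM only in 3 of the 9 cells of cluster 4, and Klf1 only in 2 of them. Gata2, Gfi1b and Meis1 were found in 8, 5 and 12 cells of the 63, and Klf4 in 13, 9 of them in cluster 1. Cluster 3 had fewer genes per cell and 47.5% ± 5.26 of its TPM in 4 granulocyte genes, which lowers the TPM of every other gene there.

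**Figure D2:**
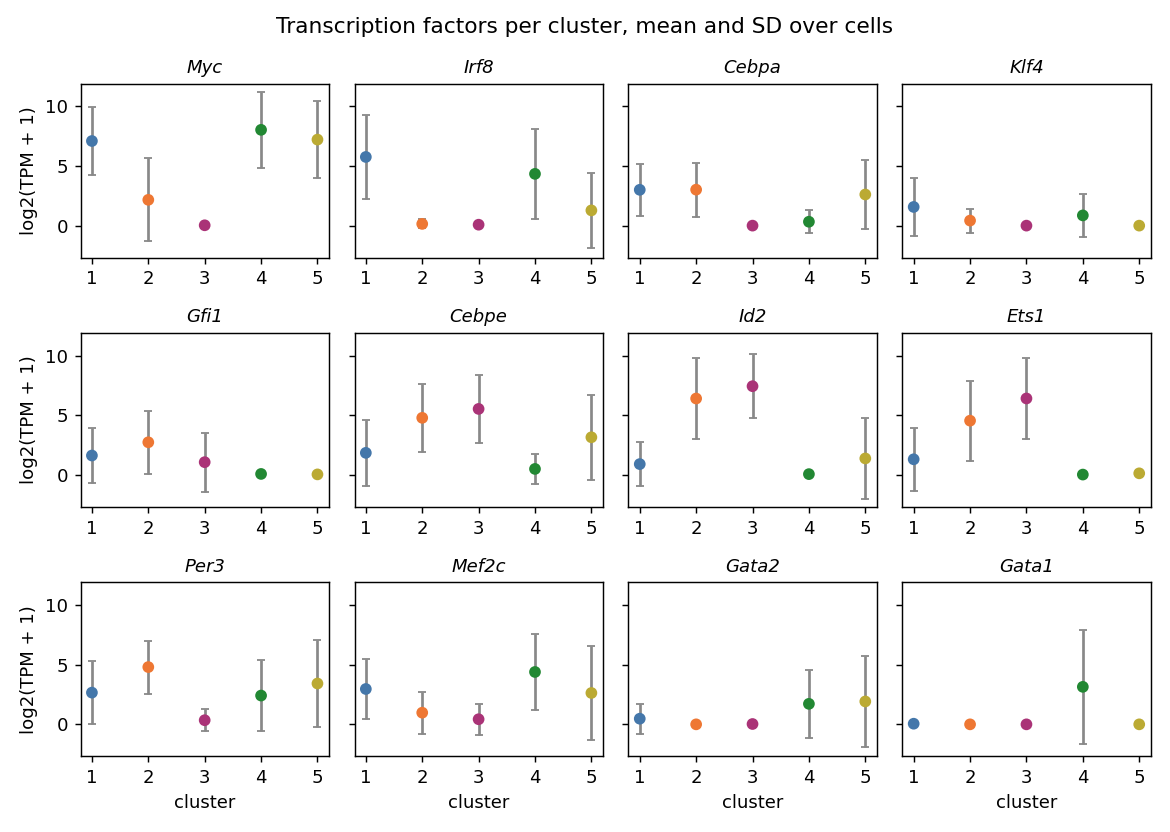
Mean log2(TPM + 1) of 12 transcription factors (y axis) in clusters 1 to 5 (x axis), with bars of 1 SD over cells. Myc and Irf8 are at 0.03 and 0.08 in cluster 3, where Cebpe, Id2 and Ets1 are at 5.54, 7.45 and 6.42.

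Pairs of factors named in advance were compared for presence in the same cell, at 1 TPM, with 10000 random gene pairs of like detection. Cebpe and Irf8 were together in 5 cells against 14.7 from the product of their shares, below all of the matched pairs (percentile 0.00). Gfi1 and Irf8 were together in 6 cells against 9.33 (percentile 2.62, inside the central 95% of matched pairs), 5 of the 6 in cluster 1. Cebpe and Gfi1 shared 18 cells against 11 (percentile 99.6), and Irf8 and Klf4 12 cells against 5.78 (percentile 99.8). Gata1 was present in both cells with Klf1 (percentile 99.99) and in 2 of the 8 cells with Gata2 (percentile 97.9, but 71.3 above 0 TPM and 92.2 at 10 TPM). Genes matched to Klf1, itself present in 2 cells, include genes present in none. For Gata1 with Klf1 the median and central 95% of matched pairs were all at 0, so any shared cell gives a high percentile. Percentiles of pairs with Klf1 therefore say little. Gata1 was found with neither Spi1 (0 cells against 1.86) nor Cebpa (0 against 1.48), at percentiles 8.66 and 13.3, inside the central 95%, and 3 Gata1 cells are too few to show exclusion. Gfi1 and Gfi1b shared 0 cells against 1.67 (percentile 6.97, also inside).

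The remaining pairs also lay inside the range of matched pairs. Cebpa and Irf8 shared 17 cells against 13.8, Meis1 and Irf8 6 against 5.33, Gata2 and Irf8 3 against 3.56, Gata2 and Cebpa 3 against 3.94, Klf1 and Fli1 1 against 1.90, and Klf1 and Cebpa 0 against 0.98. Within cluster 1 alone, an alternative chosen after seeing the data, Irf8 and Klf4 shared 9 cells at percentile 88.6. Cebpe and Gfi1 at 10 TPM shared 8 cells, at percentile 87.9.

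**Figure D3:**
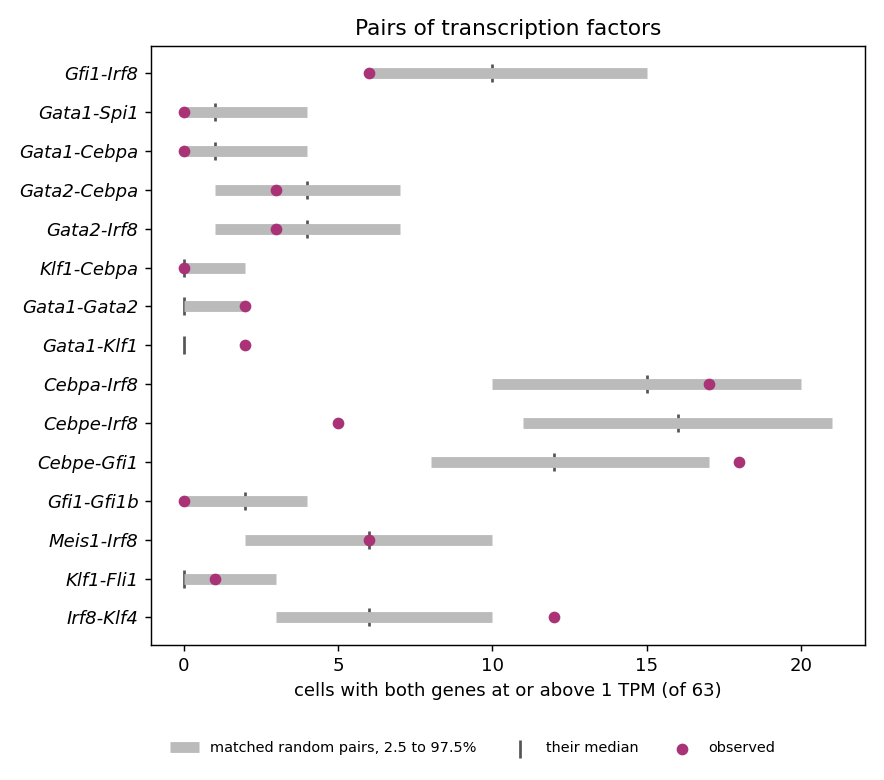
For each of 15 pairs, the point gives the cells (x axis, of 63) with both genes at or above 1 TPM, the grey bar the central 95% of matched random pairs and the tick their median. Cebpe with Irf8 (5 cells) lies left of its bar, and Cebpe with Gfi1 (18) and Irf8 with Klf4 (12) lie right of theirs.

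The last comparison counted cells that held transcripts of more than 1 lineage, with 3 members of each list at or above 10 TPM. Erythroid and primary granule genes met in 6 cells against 5.71 from the product of the shares, megakaryocyte and primary granule genes in 2 against 2.86, and megakaryocyte and erythroid genes in 1 against 0.29. The primary granule list was met in 60 of the 63 cells, so counts with it could hardly exceed the product. Among the 6 cells were cells 31, 60 and 65, with 3, 3 and 5 primary granule members at that level. Their Mpo was at 6.92, 3.11 and 11.6 TPM. Cells 2 and 24, also among the 6, had Mpo at 17720 and 28480 TPM but Car1, Gata1 and Klf1 listed at 0. Their 3 erythroid members were Car2, Blvrb and Tfrc in cell 2, and Tfrc, Minpp1 and Hemgn (named after its values were seen) in cell 24. Cell 15, with megakaryocyte and primary granule genes, had Cd9 and Serpine2 at 48.4 and 33.5 TPM, Mpo at 11681 TPM and Pf4 at 0. Erythroid and monocyte genes met in 3 cells against 5.43. Primary and late granulocyte genes met in 56 cells against 55.2, and late granulocyte and monocyte genes in 54 against 52.5 (34 against 33.1 without Ly6c2, Tyrobp and Lyz2, an alternative chosen after seeing the data). The late granulocyte list, not trimmed there, was met in 58 of 63 cells, which left little room around the product. Without Serpinb1a, Hp and Gstm1 it was met in 37 cells, 11 in cluster 1 and 10 in cluster 3. The trimmed monocyte list was met in 36, with 22 and 2 in these clusters, and the overlap of both trimmed lists was not counted. The erythroid and megakaryocyte lists were not trimmed. At 100 TPM, erythroid and primary granule genes met in 2 cells and megakaryocyte and erythroid genes in 0. No doublet caller was run on so few cells, and a pair of cells in 1 chamber would also give such counts.

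The cells with the most erythroid or megakaryocyte transcript had little of the most abundant granule transcripts. Cells 31 and 60 had Car1 (carbonic anhydrase 1) at 12476 and 4034 TPM, Gata1 at 724 and 296 TPM and Klf1 at 88.0 and 443 TPM, with Mpo at 6.92 and 3.11 TPM and Elane at 1.88 and 1.43 TPM. Cells 65 and 66 had Pf4 at 9211 and 4737 TPM, with Mpo at 11.6 and 8.20 TPM. Cell 60 also had Plac8 at 2664 TPM and cell 66 Prtn3 at 272 TPM and Lyz2 at 875 TPM. Cell 65 had Plac8 at 307 TPM and 3 primary granule members at or above 100 TPM. Cell 5 was of another kind, with the globin genes Hbb-b1 at 715 TPM and Hba-a1 at 164 TPM beside Mpo at 11382 TPM and Irf8 at 147 TPM, while Gata1 and Klf1 were listed at 0. These cells were picked by the count rule and described after their values were seen.

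**Figure D4:**
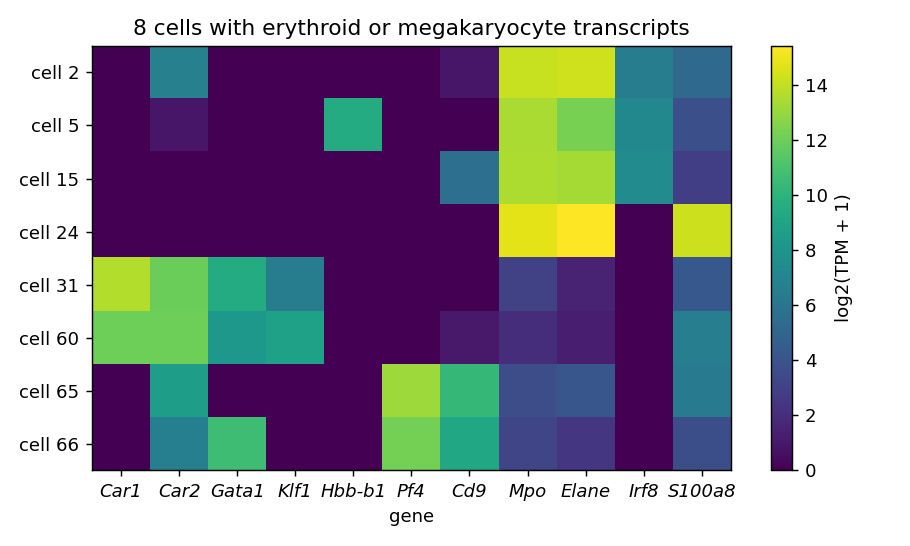
Log2(TPM + 1), as colour, of 11 genes (columns) in the 8 cells (rows) with at least 3 erythroid or 3 megakaryocyte genes at or above 10 TPM. Cells 31, 60, 65 and 66 have Mpo between 3.11 and 11.6 TPM, and cell 5 has 11382 TPM.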

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

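Values in the 3 poor-quality cells, which were left out of the main values, were looked at for signal. With no counts in the table, no limit for a count of 0 could be set, and 100 TPM for at least 3 members of the primary granule list was used in its place, a level chosen after the data were seen. All 3 cells passed it: cell 3 had 3 of 10 members at that level, cell 8 had 5 and cell 11 had 7. TPM is scaled to the same total in every cell, so with few genes listed a gene reaches this level more easily. In cell 11 all 322 genes above 0 were at or above 10 TPM. Mpo was at 101 TPM in cell 3, 53353 TPM in cell 8 and 25716 TPM in cell 11, and Elane at 218, 212 and 22129 TPM. S100a8 was at 279 TPM in cell 3, 240 TPM in cell 8 and 23492 TPM in cell 11, and S100a9 at 135, 142 and 0 TPM. In cells 3 and 8 the highest gene was Gm20594, named after its values were seen, with 10.9 and 14.9% of TPM, and Actb was at 34.3 and 77.7 TPM, against a median of 6439 TPM in the other 63 cells. Erythroid and megakaryocyte lists had 0 members at 1 TPM in these 3 cells. No explanation was tested.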

How the results depend on the processing

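Results have no test, so an alternative is said to move a share or a count of cells when it lies outside the 95% binomial interval of the main value, a level when it moves by over 1 SD, and a percentile when it enters or leaves the central 95% of the matched lists or pairs. Settings that raise levels to 1% of a gene's mean, leave out cells under 2500 genes or list members, or take cluster 1 alone were chosen after seeing the data. The 4 cells under 2500 genes, called shallow below although read depth is unknown, all belong to cluster 3. The effect of leaving them out therefore cannot be told from that of removing late-granulocyte-like cells. No paired analysis was possible because the results come from no test between groups. The number of genes per cell, the shares of cells with a list and the counts of cells with 2 lists followed the detection level, by construction. For the others below the cause was not tested, and is given only where stated.

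At or above 10 TPM the median was 3264 genes, Kit was in 46.0% of cells, and shares with lists were 63.5% (stem and multipotent progenitor), 4.76% (megakaryocyte), 9.52% (erythroid), 92.1% (late granulocyte) and 6.35% (dendritic). Above 0 TPM, Kit was in 74.6% and Cd34 in 68.3%. With at least 2 members, shares were 95.2% (stem and multipotent progenitor), 42.9% (megakaryocyte), 57.1% (erythroid), 55.6% (dendritic), 15.9% (basophil and mast) and 19.0% (lymphoid progenitor). With at least 5 they were 41.3% (stem and multipotent progenitor), 3.17% (megakaryocyte), 3.17% (erythroid), 84.1% (monocyte) and 0% (dendritic). With levels raised to 1% of the mean, 82.5% had the late granulocyte list.

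Cells with 2 lists, at or above 1 TPM, were 63 for primary granule with late granulocyte and 59 for late granulocyte with monocyte. Erythroid genes met primary granule genes in 17 cells, late granulocyte genes in 17 and monocyte genes in 14. Megakaryocyte genes met these lists in 9, 9 and 7. Dendritic genes met each of the 3 in 11. At or above 100 TPM, primary with late granulocyte genes gave 45 cells, late granulocyte with monocyte 44, erythroid with primary granule 2 and with late granulocyte 1. Megakaryocyte genes met erythroid, late granulocyte and monocyte genes in 0 cells, and dendritic genes met primary granule, late granulocyte and monocyte genes in 0. With at least 2 members, primary with late granulocyte genes gave 63, and monocyte genes with either 60. Erythroid genes met primary granule, late granulocyte, monocyte and dendritic genes in 23, 23, 20 and 15 cells. Megakaryocyte genes met primary granule, late granulocyte, monocyte, dendritic and erythroid genes in 22, 22, 20, 10 and 9 cells. Dendritic genes met primary granule, late granulocyte and monocyte genes in 27, 27 and 24.

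The spread percentile of the stem and multipotent progenitor list left the central 95% upward with pseudocount 10 (98.4) and without the shallow cells (99.4). That of the eosinophil list did so with pseudocount 10 (99.3), with rescaling (99.6) and without the shallow cells (97.6). The other 54 settings of list spread left each list on its side. Of the factor pairs, Gata1 with Gata2 fell back inside it above 0 TPM (71.3) and at 10 TPM (92.2), as did Cebpe with Gfi1 at 10 TPM (87.9) and Irf8 with Klf4 in cluster 1 alone (88.6). Gfi1 with Irf8 went to 2.45 without the shallow cells. The other 78 settings of pairs left them on their side.

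The division into clusters moved under most settings. The adjusted Rand index with the clusters was 0.51 with 1000 genes, 0.48 with 250, 0.54 with pseudocount 10, 0.41 with average linkage, 0.44 with the silhouette rule and 0.50 without the shallow cells. Average linkage and the silhouette rule gave 2 clusters. Of the settings for single transcription factors, 51 moved the difference between the highest and lowest cluster mean by under 1 SD and 3 by more, all without the shallow cells: Gata1 went from 3.15 to 5.66, Gata2 from 1.92 to 4.01 and Gfi1b from 1.96 to 5.40. Without the shallow cells the clusters were made anew and numbered 6. Gata1 was listed at 0 throughout clusters 2, 3 and 5, so with the clusters unchanged its difference could not have moved. Read depth is unknown, so its part in the shares of cells with a gene cannot be given.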

Other observations

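Tests of carried-over RNA and of a few genes taking the signal were chosen only after the result was seen, and so were the S100a8 count, the housekeeping comparison and the alternatives named as such above. Cell cycle genes had been kept out of the clustering, and S phase and G2/M lists differed over it. The S phase list averaged 5.50 ± 1.01 in cluster 1, 4.42 ± 1.67 in cluster 2 and 1.36 ± 1.16 in cluster 3. The G2/M list averaged 4.10 ± 2.09, 5.09 ± 1.73 and 4.72 ± 2.51. In cluster 3 the members of the S phase list were in 0 to 8 of 10 cells (Tyms, named after its value was seen, in 8), among them Mcm2 in 0, Mcm5 and Cdc45 in 2, Mcm3 in 3, Pcna in 4 and Rrm2 in 6. In the same 10 cells, the members of the G2/M list were in 3 to 9 (Cdc20, also named after its value was seen, in 3), among them Aurka in 6, Top2a, Ccnb1 and Cdk1 in 8, and Ube2c and Birc5 in 9. Clusters 4 and 5 had S phase means of 5.70 ± 1.13 and 4.46 ± 2.03 and G2/M means of 3.13 ± 2.19 and 2.49 ± 1.97. Over all 63 cells both lists spread more than every matched random list. Cluster 3 also had the fewest genes per cell.

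The immediate early and stress list, which handling of tissue can raise, was found in 49 of 63 cells, with a spread at percentile 99.98. It ranged from 0.05 to 5.59 within cluster 4 and from 0.22 to 5.47 within cluster 1. Fos was in 43 cells and Jun in 49. A Y-linked gene was at or above 1 TPM in 48 of 63 cells (76.2%), and 3 of the 4 such genes in 4 cells. Xist was below 1 TPM in all 63. The spread of the Y-linked list lay at percentile 64.3 and that of Xist at 46.6.

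Some genes of other tissues had a value in every cell. Among 310 genes above 0 in all 63 cells, 103 had a median under 50 TPM, such as Nanog (20.3 TPM), Tyr (17.6 TPM) and Chrna1 (7.61 TPM), named after their values were seen. The 103 were defined by these values alone, with no tissue criterion. The rescaling by the median ratio used the same 310 genes. Of the 102 with a transcript sequence, 67.6% shared at least 50 of their 31-base words with 10 or more other genes, against at most 27.5% in 10000 random sets matched on mean expression and transcript length. Reads of repeated sequence assigned to these genes are a candidate explanation. Other causes of the remaining genes were not tested, and no biological explanation was tested.

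Granulocyte transcripts were listed at low level in most cells outside clusters 2 and 3. In cluster 4, S100a8, S100a9, Ngp and Camp had medians of 18.3, 8.92, 6.37 and 4.53 TPM, which are 0.0437, 0.0416, 0.0270 and 0.0270% of their means over all cells. The highest of these ratios was 1.62 times the lowest, near the common ratio that RNA or reads carried over from other cells would give, and 0 of the 4 transcripts shared sequence in this way, which argues against repeats. The ratios were less even elsewhere, at 0.0695% for Lcn2 and 0.0155% for Chil3 in cluster 4 (medians of 2.38 and 0.59 TPM) and from 0.0249 to 0.0808% for the same 4 genes in cluster 1, with S100a8 the highest. Part of the S100a8 signal is not covered, since its median in cluster 5 was at 0.136% of its mean against 0.0144 to 0.0266% for the other 3, and in 6 of the 32 cells of clusters 1 and 5, S100a8 as a share of its mean was at least 10 times the other 3, with values from 171 to 8387 TPM, and carried-over RNA of mixed origin would have raised the others too. No biological explanation was tested, and whether any carry-over arose on the chip, in amplification or in sequencing stays open.

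Ribosomal protein transcripts were lower in cluster 3: over 76 genes with Rpl or Rps symbols present in over 50 cells, a set defined after the pattern was seen, the mean log2(TPM + 1) was 6.75 ± 0.97 in its 10 cells and 10.63 ± 0.45 in the other 53. With S100a8, S100a9, Ngp and Camp removed and the rest rescaled, the other cells still exceeded cluster 3 by 3.10, more than the sum of both SDs (0.99 and 0.34), which argues against these 4 genes as the whole cause. Among the other 53 cells, the 17 with the most genes exceeded the 17 with the fewest by 0.22, which argues against gene detection as such, although the cells with the fewest genes there still had a median of 3763, above the 2911 of cluster 3. The housekeeping list was at 8.16 ± 1.02 there against cluster means of 10.11 to 10.53 elsewhere, and at 8.20 ± 1.00 against 9.46 to 9.95 without its members Rplp0 and Eef1a1, with no correction for the 4 genes' 47.5% of TPM, while its member Actb was at 13.72 ± 0.44 against 12.29 to 13.27. A lower content of ribosomal protein transcript in these cells and a wider loss of RNA both stay open, and the second was not tested.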
